A study of Bos taurus with 34 samples.

How the data were processed

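Bovine liver RNA was extracted with a column kit and sequenced from TruSeq libraries (18 samples) or SMARTer libraries (16 samples), per the labels' protocols. Samples were grouped by the genotype and, in the TruSeq experiment, the sire that the labels give. The submitters' processing notes name HISAT2 2.1.0, featureCounts, Subread, edgeR and the ARS-UCD1.2 build, without giving the role or order of each. The header of the SMARTer count table names featureCounts 1.6.2 with Ensembl release 100 gene models, read pairs, a minimum mapping quality of 10 and strand-aware counting of exons, per the file headers. Counting of the TruSeq libraries is not described in that header.

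The tables hold 70 columns of per-library values in 4 tables. Their names are animal numbers that no sample label holds, so none could be matched to a sample, and none was used in any step. The comparison table and the TruSeq count table each name 18 animals, of which 17 are shared and 1 is found in each alone. Whether the comparison was made on the 18 labelled samples is therefore open. Depth per sample was not used here for the same reason, and the precision of a value is known from the authors' p-value only.

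The authors deposited a comparison of slick with free animals for the TruSeq libraries. It gives a log2 fold change, an average log2 CPM, an F score, a p-value and an adjusted p-value per gene, per the file headers. The authors' F score and p-value together imply 18.7 denominator degrees of freedom, the same in 500 genes examined. The model terms, among them whether sire was included, are not given in the sources used here. The sign of the deposited log2 fold change was taken from the name of the table. The table has 14246 rows, of which 85 repeat a gene under a further symbol with the same values, and 14161 genes were kept. The deposited adjusted p differs from a Benjamini-Hochberg adjustment over these genes by up to 0.0141, so it was made over another set of genes. Gene lengths and coordinates came from the deposited annotation columns of the count tables, which hold 27607 genes; the length is another deposited value with no sample behind it.

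The design fixed before the data were examined had planned quasi-likelihood fits of the raw counts for SLICK against FREE with sire as a covariate, S2 against S1, the sires, and the interaction of genotype and sire. None of these could be fitted without library groups. The deposited p-values were used in their place for SLICK against FREE, and the other comparisons were not analysed. The planned camera test on library values was replaced by cameraPR of limma 3.58.1 in R 4.3.3, which needs only a score per gene. The score was the normal quantile of the two-sided deposited p with the sign of the fold change.

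Gene lists were fixed before the data were examined: 23 pathway lists and 13 cell type lists, with 1106 distinct symbols, of which 950 were measured. Lists with under 5 measured genes (2 lists, skin keratinocyte with 3 and sex-linked with 0) were not tested. The inter-gene correlation was 0.01, and p-values were adjusted by Benjamini-Hochberg over the 34 lists tested. Adjustment over a list alone used the deposited p-values of its members. Intervals of medians are from 10000 bootstrap draws over genes and cover the spread between genes, not between animals. Random lists were drawn 10000 times with the same number of genes per expression level. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

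The genes named were chosen by a rule fixed in advance. It took PRLR, up to 10 genes in each direction with the largest change among those past an adjusted p of 0.05 with an average of at least 0 log2 CPM, and the 5 genes with the smallest p in the authors' table. It also took the 4 members with the smallest p of each list that passed, and the 3 with the smallest p of the prolactin receptor, growth hormone and heat shock lists. Some genes that the rule took are not reported here. The list test was tested on simulated scores for the 14161 genes of the SLICK against FREE comparison. It recovered 98.0% of lists shifted by 1 score unit in 20 simulations, and 4.81% of unshifted lists had a p under 0.05. Both shares hold for the simulated scores only. The correlation within the real lists could not be estimated, so the simulations cannot show how often the list test errs on them.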

Results

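Liver RNA was sequenced in cattle carrying 0, 1 or 2 copies of the SLICK1 allele of PRLR, the gene of the prolactin receptor. The allele truncates the receptor and is known for a short, sleek coat and a better control of body temperature in the heat. The series has 34 liver samples in 2 experiments. In the TruSeq experiment, 18 samples came from daughters of the slick bulls Blanco and Lone Ranger. Of these, 10 carried 1 copy of the allele (SLICK, 5 from each bull) and 8 carried 0 copies (FREE, 7 of Lone Ranger and 1 of Blanco). In the SMARTer experiment, 16 samples came from animals with 1 copy (S1, 5 samples) or 2 copies (S2, 11 samples). The library columns of the tables carry animal numbers that the sample labels do not hold, so no library could be tied to its group. Depth per sample, S2 against S1 and the sire comparison are therefore not analysed here. The comparison of SLICK with FREE rests on the authors' deposited table of 14161 genes, whose name sets slick against free. Positive values are read from that name as higher in SLICK, a direction that could not be checked against single libraries.

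The comparison of SLICK with FREE asks which liver genes differ between daughters with 1 copy of the allele and daughters with 0. Genes of the interferon response, immediate early genes, inflammatory genes and bile duct markers were lower as lists in SLICK liver. As lists, genes of fatty acid oxidation, xenobiotic metabolism, amino acid catabolism and the nuclear encoded respiratory chain were higher, although 0 members of these 4 lists passed over all genes. Median log2 fold changes of these lower lists were -1.09 (interferon), -0.45 (immediate early), -0.35 (inflammatory) and -0.42 (bile duct). Those of the higher lists were 0.30 (fatty acid oxidation), 0.37 (xenobiotic), 0.24 (amino acid) and 0.14 (nuclear encoded respiratory chain). Genotype is partly confounded with sire, and whether the authors' model held sire is not given in the sources used here. The list differences therefore cannot be credited to the allele alone, and whether 1 animal carries any of them is open. PRLR itself was nearly level between the genotypes.

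PRLR lies on chromosome 20 of the ARS-UCD1.2 assembly, from 38971752 to 39100563 on the + strand (ENSBTAG00000025035). Its log2 fold change in the authors' deposited table was -0.05, with an unadjusted p of 0.791 and an adjusted p of 0.936. The allele alters the coding sequence, so this transcript level does not check the genotype labels. The average level of PRLR in the authors' deposited table was 5.89 log2 CPM.

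By the adjusted p of the authors' deposited table, 71 of the 14161 genes changed at a threshold of 0.05, of which 13 rose and 58 fell in SLICK. The share that fell was 81.7% (Wilson 95% interval 71.2% to 89.0%, treating genes as independent, which they are not). Of the genes that fell, 38 did so by at least 1 log2 unit, against 2 of those that rose. The median log2 fold change in the authors' deposited table was -1.24 for the genes that fell and 0.55 for those that rose. At an unadjusted p under 0.05 the authors' deposited table held 2267 genes, against 708.05 expected with no effect. These divided into 1022 higher and 1245 lower genes. The smallest adjusted p in the authors' deposited table was 0.0210, and 41 genes shared the value 0.0486 just under the threshold.

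The 5 genes with the smallest p in the authors' deposited table all fell. EHF, an epithelial transcription factor of the ETS family, fell by 1.24 log2 units in the authors' deposited table (p = 4.05e-06, adjusted p = 0.0210). It lies on chromosome 15 from 65186293 to 65227768 (ENSBTAG00000017150). CRYAB, a small heat shock protein, fell by 2.24 log2 units in the authors' deposited table, which is 4.72-fold (chromosome 15, 22242326 to 22246349). The vitamin D receptor VDR fell by 1.33, the transcription factor MYC fell by 1.05 and the immunoglobulin receptor FCAMR fell by 2.11 log2 units in the authors' deposited table. VDR and FCAMR averaged -0.14 and -0.23 log2 CPM, under the bound of 0 used for the largest changes. All 5 had an adjusted p of 0.0210 in the authors' deposited table.

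Among genes with an average of at least 0 log2 CPM, the largest falls in the authors' deposited table were those of ISG12(B), with a log2 fold change of -4.44, and the meiotic cohesin subunit REC8, with -4.39. The fatty acid elongase ELOVL7 fell by 3.06 and HERC6, a HECT-type protein induced by interferon, fell by 2.46 in the authors' deposited table. The lipoprotein receptor LRP8 fell by 2.24, the myeloid receptor TREM2 fell by 2.14 and ANKRD1 fell by 1.93 log2 units in the authors' deposited table. ISG20, an exonuclease induced by interferon, fell by 1.88, and LYPD1 fell by 1.74 in the authors' deposited table. ISG12(B) and the OAS1 genes have close paralogs, so reads shared between copies may make their values uncertain, which was not tested.

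Genes that rose did so by less. SEC14L3, a lipid-binding protein, rose by 1.42 log2 units in the authors' deposited table (2.68-fold, chromosome 17, 69431412 to 69441202). ASB11 rose by 0.65, DHRS7 by 0.64 and PNMA2 by 0.61 log2 units in the authors' deposited table. DMGDH, the mitochondrial dimethylglycine dehydrogenase, rose by 0.61 in the authors' deposited table and had the smallest p of the genes that rose (9.45e-06, adjusted p = 0.0210). GALT of galactose metabolism rose by 0.55, PCBD1 of tetrahydrobiopterin recycling by 0.51 and the hydroxylysine kinase HYKK by 0.51 in the authors' deposited table. GCAT of threonine catabolism rose by 0.48 and CRYL1 by 0.47 log2 units in the authors' deposited table.

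**Figure D1:**
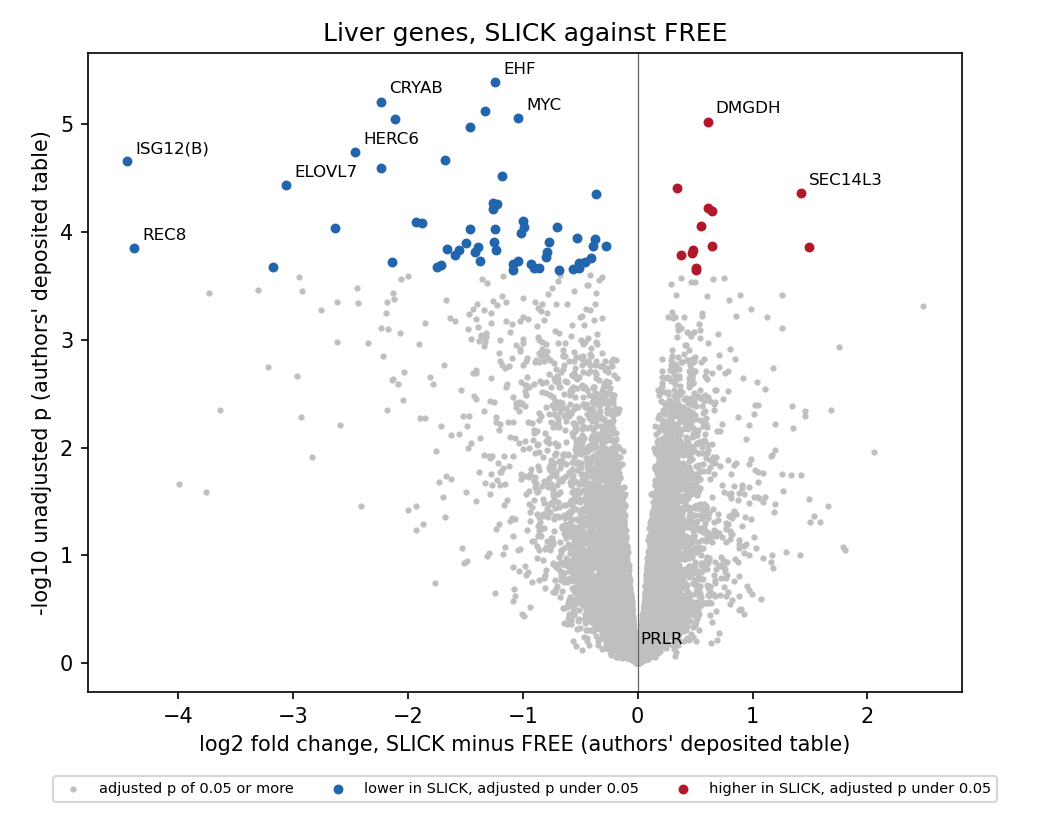
Each point is 1 of 14161 genes, with the log2 fold change of SLICK minus FREE on the horizontal axis and -log10 of the unadjusted p on the vertical axis, both from the authors' deposited table. Blue points are the 58 genes that fell and red points the 13 that rose at an adjusted p under 0.05; the blue points reach -4.44 (ISG12(B)) and SEC14L3 among the named red points stands at 1.42.

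Gene lists fixed before the data were examined were tested with cameraPR of limma on the signed scores of the deposited p-values. Of 34 lists with at least 5 measured genes, 18 passed an adjusted p of 0.05, 11 higher and 7 lower in SLICK. An estimated inter-gene correlation was not possible because per-library values were not used. With the preset correlation raised from 0.01 to 0.05, 14 of the 18 lists passed, and with 0.10, 10 passed. The correlation within a list may be higher than these settings, so the adjusted p of any list may overstate the evidence.

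Interferon response genes were the lowest group. All 41 measured members had a negative log2 fold change in the authors' deposited table, 39 of them with an unadjusted p under 0.05. Adjusted over all genes 4 fell, and adjusted over the list alone 38 fell and 0 rose. The 4 were HERC6, ISG20, the guanylate-binding protein GBP4 (-1.59 for the copy that passed) and OAS1Z (-1.71), an oligoadenylate synthetase, in the authors' deposited table. A further gene with the symbol GBP4 had a log2 fold change of -1.11 and an adjusted p of 0.318 in the authors' deposited table. The list median was -1.09 (95% bootstrap interval over genes -1.28 to -0.84), and the cameraPR adjusted p was 8.79e-30. It stayed at 2.26e-08 with a correlation of 0.10. The correlation within this list could not be estimated and may be higher than 0.10, so both adjusted p may overstate the evidence.

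Immediate early genes, which cells induce within minutes of a stimulus, were lower as a list. Of 30 measured, 1 fell adjusted over all genes and 13 fell adjusted over the list alone. The list median was -0.45 (interval -0.71 to -0.34) and the cameraPR adjusted p was 1.52e-12. MYC was the member that passed over all genes. JUN had a log2 fold change of -0.75, FOSL1 of -3.30 and CCN2 of -1.18 in the authors' deposited table. Their adjusted p ran from 0.0552 to 0.0575. FOSL1 averaged -0.47 log2 CPM, under the bound of 0 used for the largest changes.

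Inflammatory cytokine and NF-kB response genes were also lower as a list, with a median of -0.35 (interval -0.48 to -0.09) and a cameraPR adjusted p of 2.78e-06. Of 37 measured, 1 fell adjusted over all genes, and 9 fell and 1 rose adjusted over the list alone. RELB, a subunit of NF-kB, fell by 0.69 log2 units in the authors' deposited table. The log2 fold changes of the endotoxin receptor TLR4 (-0.57) and the chemokine CXCL10 (-1.06) did not pass over all genes in the authors' deposited table. Antigen presentation genes had a median of -0.20 over 26 genes and a cameraPR adjusted p of 0.0133, or 0.0884 with a correlation of 0.05. No member passed over all genes or adjusted over the list alone, where 0 rose and 0 fell. The immunoproteasome subunits PSMB8 and PSMB9 had log2 fold changes of -0.43 and -0.42 in the authors' deposited table.

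Cholangiocyte markers, which mark the lining of the bile ducts, were lower as a list of 13 genes. The median was -0.42 (interval -0.80 to -0.07), with a cameraPR adjusted p of 5.20e-05, or 0.00983 with a correlation of 0.10. Adjusted over all genes 0 passed, and adjusted over the list alone 5 fell. CLDN4, a tight junction protein, had a log2 fold change of -1.67, SPP1 of -2.44 and the keratin KRT7 of -1.03 in the authors' deposited table. Hepatocyte markers, given further on, passed as a higher list, and the other 9 cell type lists tested did not pass. Medians of these 9 were 0.00 for 23 T and NK cell genes, -0.01 for 14 B and plasma cell genes, 0.06 for 18 Kupffer cell and macrophage genes and 0.08 for 18 endothelial genes. They were -0.08 for 22 stellate cell and fibroblast genes, -0.40 for 9 neutrophil genes, -0.01 for 9 adipocyte genes, -0.10 for 6 erythroid genes and -0.16 for 6 skeletal muscle genes. The smallest cameraPR adjusted p among these 9 lists was 0.0867, for the stellate cell list.

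Prolactin receptor signalling genes were lower as a list of 33, with a median of -0.10 (interval -0.16 to -0.03). The cameraPR adjusted p was 0.00215, or 0.0419 with a correlation of 0.05 and 0.148 with 0.10. MYC fell adjusted over all genes, and 7 fell adjusted over the list alone. The log2 fold change of the feedback inhibitor SOCS3 (-0.68) did not pass over all genes in the authors' deposited table. Of the 33 genes, 6 are also in other lists, and without these the prolactin list no longer passed. The growth hormone and IGF axis did not pass (22 genes, median 0.02, cameraPR adjusted p = 0.463), with 0 members passing over all genes and 0 adjusted over the list alone. The growth hormone receptor GHR had a log2 fold change of 0.40, IGF2 of 0.32 and SOCS2 of -0.60 in the authors' deposited table, with adjusted p from 0.201 to 0.213.

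Heat shock chaperones did not pass as a list (40 genes, median -0.04, cameraPR adjusted p = 0.575). Their median lay at percentile 0.1 of the random lists matched on expression. With scores centred within expression levels, an alternative chosen after seeing the data, the list passed as lower. CRYAB was the member that fell, over all genes and adjusted over the list alone (1 in each case). The next smallest p in the authors' deposited table were those of HIKESHI, a nuclear import factor for HSP70 (log2 fold change 0.23), and the co-chaperone DNAJA2 (0.15), and neither passed. Oxidative stress response genes had a median of -0.10 over 31 genes and a cameraPR adjusted p of 0.0368, or 0.174 with a correlation of 0.05. SRXN1, which repairs peroxiredoxins, fell by 1.09 log2 units in the authors' deposited table and was the 1 member to pass over all genes. Adjusted over the list alone, 4 fell and 2 rose. PRDX1 had a log2 fold change of -0.42, TXN of -0.54 and the mitochondrial SOD2 of 0.30 in the authors' deposited table.

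**Figure D2:**
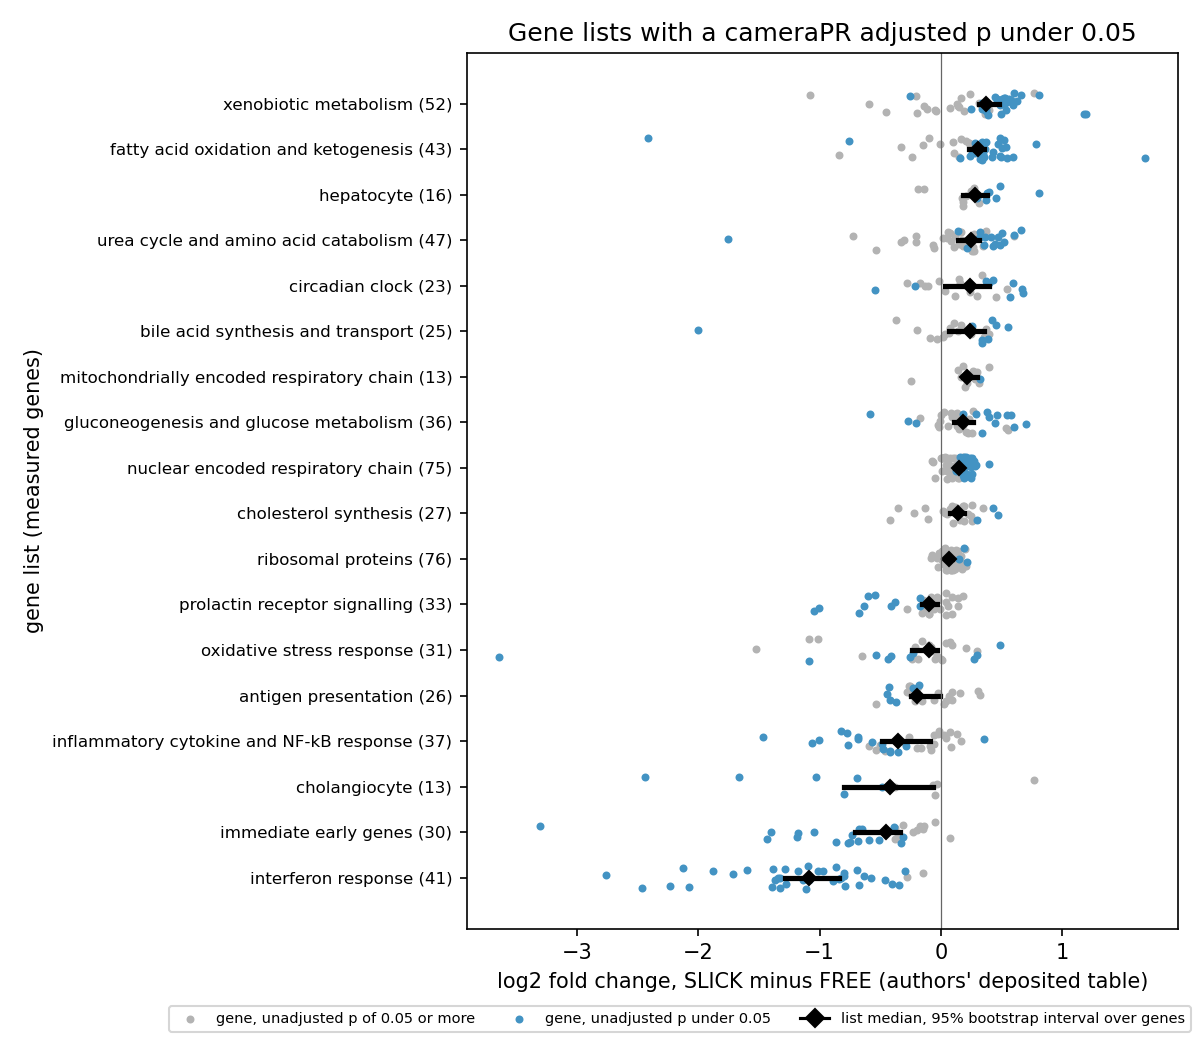
Log2 fold changes of SLICK minus FREE from the authors' deposited table for the measured genes of the 18 lists that passed, with 1 point per gene in blue where the unadjusted p was under 0.05 and in grey otherwise. Diamonds are list medians and bars their 95% bootstrap intervals over genes; medians run from -1.09 for the interferon response to 0.37 for xenobiotic metabolism.

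Fatty acid oxidation and ketogenesis genes were higher as a list. Of 43 measured, 0 passed adjusted over all genes, and 22 rose and 1 fell adjusted over the list alone. The median was 0.30 (interval 0.23 to 0.36) and the cameraPR adjusted p was 9.17e-11. In the authors' deposited table the log2 fold change was 0.34 for ETFB, an electron carrier of beta-oxidation, 0.48 for the thiolase ACAA1, 0.37 for the carnitine palmitoyltransferase CPT2 and 0.52 for the isomerase ECI1. Xenobiotic metabolism genes had the highest median, 0.37 over 52 genes (interval 0.32 to 0.48), with a cameraPR adjusted p of 8.16e-11. Adjusted over all genes 0 passed, and adjusted over the list alone 19 rose and 0 fell. The cytochromes P450 CYP2E1, CYP3A4 and CYP2C87 had log2 fold changes of 0.81, 0.35 and 1.18 in the authors' deposited table. Reads shared between P450 paralogs may make single members uncertain, which was not tested.

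Urea cycle and amino acid catabolism genes were higher as a list of 47 (median 0.24, interval 0.14 to 0.31). Their cameraPR adjusted p was 2.78e-06, or 0.0398 with a correlation of 0.10. Over all genes 0 passed, and adjusted over the list alone 6 rose and 0 fell. GLDC of glycine cleavage had a log2 fold change of 0.66, the urea cycle enzymes ASS1 and CPS1 of 0.60 and 0.49, and HGD of tyrosine breakdown of 0.43 in the authors' deposited table. Nuclear encoded respiratory chain genes moved little but together. Their median was 0.14 over 75 genes (interval 0.12 to 0.17), and 71 were positive. The cameraPR adjusted p was 8.00e-15, or 0.00241 with a correlation of 0.10. Over all genes 0 passed, and adjusted over the list alone 0 rose and 0 fell. ATP5MC1 of the ATP synthase had a log2 fold change of 0.29 and the complex I subunits NDUFB6, NDUFA9 and NDUFS7 of 0.21, 0.18 and 0.27 in the authors' deposited table. Mitochondrially encoded genes had a median of 0.21 over 13 genes (cameraPR adjusted p = 0.00215, or 0.0545 with a correlation of 0.10), with 0 passing over all genes and 0 adjusted over the list alone.

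Hepatocyte markers were higher as a list of 16 (median 0.28, interval 0.18 to 0.38). Their cameraPR adjusted p was 9.85e-06, or 0.00765 with a correlation of 0.10. Adjusted over the list alone 5 hepatocyte markers rose and 0 fell, against 0 over all genes. The apolipoprotein APOC3 had a log2 fold change of 0.46 and transferrin (TF) of 0.40 in the authors' deposited table. Gluconeogenesis and glucose metabolism genes had a median of 0.18 over 36 genes (cameraPR adjusted p = 1.61e-05, or 0.0398 with a correlation of 0.10). Of these genes, 5 rose and 1 fell adjusted over the list alone, against 0 over all genes. TKFC had a log2 fold change of 0.57 and PFKFB3, a driver of glycolysis, of -0.58 in the authors' deposited table. Bile acid synthesis and transport genes had a median of 0.24 over 25 genes (cameraPR adjusted p = 8.30e-04, or 0.0811 with a correlation of 0.10). Adjusted over the list alone 4 rose and 1 fell, against 0 over all genes. The bile acid importer SLC10A1 had a log2 fold change of 0.45 in the authors' deposited table. There SLC51A, a subunit of the basolateral exporter, was 3.99-fold lower without passing over all genes. SLC51A averaged -0.52 log2 CPM, under the bound of 0 used for the largest changes.

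Circadian clock genes had a median of 0.24 over 23 genes (cameraPR adjusted p = 0.00919, or 0.0645 with a correlation of 0.05). Adjusted over the list alone 3 rose, against 0 over all genes. PER1 had a log2 fold change of 0.68, CRY2 of 0.59 and TSC22D3, which glucocorticoids induce, of 0.43 in the authors' deposited table. Cholesterol synthesis genes had a median of 0.14 over 27 genes (cameraPR adjusted p = 0.0189, or 0.109 with a correlation of 0.05), with 0 passing over all genes and 0 adjusted over the list alone. Ribosomal protein genes had a median of 0.07 over 76 genes (cameraPR adjusted p = 8.65e-05, or 0.148 with a correlation of 0.10), again with 0 and 0. Across all genes, log2 fold change rose with expression level (Spearman rho = 0.22; genes are not independent replicates). With the scores centred within expression levels, 6 of these lists no longer passed in the higher direction: hepatocyte, gluconeogenesis, bile acid, cholesterol synthesis, mitochondrially encoded and ribosomal. The ribosomal and cholesterol scores then lay below those of other genes. The difference in score from other genes also shrank for lists that kept their call, from 1.59 to 0.73 for xenobiotic metabolism and from 1.21 to 0.59 for amino acid catabolism.

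The remaining lists did not pass. Acute phase proteins had a median of 0.07 over 33 genes (cameraPR adjusted p = 0.0679), and adjusted over the list alone 0 passed. Medians were -0.09 for 27 unfolded protein response genes, 0.02 for 32 genes of fatty acid and triglyceride synthesis, 0.03 for 19 genes of thyroid hormone action and thermogenesis, and 0.01 for 43 cell cycle genes. Adjusted over the list alone, 2 unfolded protein response genes fell. The median of that list lay at percentile 0.02 of the random lists matched on expression, and with centred scores the list passed as lower. The p-values of single genes are those of the authors' model, and cameraPR treats the genes of a list as correlated by a preset amount.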

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

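Apart from the adjusted p threshold of 0.10, every alternative here was chosen after seeing the data. At an adjusted p under 0.10, 392 genes passed (117 higher, 275 lower), more than 1.5 times the 71 at 0.05, as the looser threshold makes it. The lower share was 70.2% there and between 76.6% and 79.7% under the other 3 alternatives. With the adjustment recomputed over the deposited genes, 90 passed, all 71 among them. The next counts also rest on a recomputed adjustment, so 90 is their reference. With genes averaging at least 0 log2 CPM 77 passed, against 61 of these genes by the deposited adjusted p. Without the interferon list 79 passed, against 67 by the deposited adjusted p. The 67 still hold ISG12(B), an interferon-stimulated gene by its name that the list lacks. The count therefore does not give the calls that are free of the interferon response. For PRLR, subtracting the median of all genes gave -0.04, on the same side.

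With an inter-gene correlation of 0.10, 10 of the 18 lists passed, by construction of the stricter setting. The count stayed within 1.5 times under the other 6 alternatives, from 14 to 19. Of 236 results of single lists under alternatives, 197 kept direction and side of the threshold, 21 lost the call, 4 gained it and 14 turned in direction. Among the lost calls were those of the antigen presentation, bile acid, cholesterol synthesis and ribosomal lists with the log2 fold change as the score. The gained calls were lower scores in SLICK: heat shock chaperones and the unfolded protein response with scores centred within expression levels, and neutrophil markers with the log2 fold change as the score and with genes averaging at least 0 log2 CPM. Of the 14, 2 were of lists that had passed: with scores centred within expression levels, the difference from other genes was -0.34 for ribosomal proteins and -0.18 for cholesterol synthesis. The other 12 were of lists that had not passed. With centred scores the difference was -0.55 for acute phase proteins, -0.21 for fatty acid and triglyceride synthesis, -0.0930 for the growth hormone and IGF axis and 0.20 for cell cycle genes. With the log2 fold change as the score it was -0.0026 for acute phase proteins, 0.0158 for adipocyte markers, 0.00136 for B and plasma cell markers and 0.0499 for cell cycle genes. With ranks it was 0.0644 percentile points for adipocyte, 0.851 for cell cycle and 1.12 for Kupffer cell and macrophage genes. Without members of other lists it was 0.0849 for cell cycle genes. The cause was not tested. Interferon, immediate early, inflammatory, cholangiocyte, fatty acid oxidation, xenobiotic, urea cycle and nuclear respiratory chain lists passed under all 7.

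No paired analysis was possible because the library columns carry no replicate number. For the same reason the alternatives chosen in advance on normalization, filters, tests, covariates, estimated correlation, single sires and single libraries left out were not run, nor were regroupings of the samples or any alternative for S2 against S1, the sires, the interaction or the correlation of both experiments. Whether 1 animal carries a result is therefore open, and depth limits could not be assessed.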

Other observations

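Of the tests below, those of an offset in scaling, of the implied standard error, of the hepatocyte share, of the expression trend and of the symbol families were chosen after the results were seen. Genes were grouped into 171 families by the letters of their symbols, with at least 10 measured members each, and tested with cameraPR. At an adjusted p under 0.05, 12 families passed, 8 higher and 4 lower in SLICK, and 4 passed with a correlation of 0.05. Those 4 were CYP, HSD, NDUFA and CXCL. Cytochromes P450 (CYP, 35 genes, median log2 fold change 0.36, adjusted p = 1.46e-05) and the hydroxysteroid dehydrogenase symbols (HSD, 15 genes, median 0.31, adjusted p = 3.02e-04) were higher in SLICK, as were the complex I subunits of the NDUFA symbols (14 genes, median 0.14, adjusted p = 7.19e-04). CXC chemokines (CXCL, 10 genes, median -0.51) were lower, with an adjusted p of 0.00766, or 0.0495 with a correlation of 0.05. The other 8 families, lost with that correlation, were COX, COQ, NDUFB, ALDH and MGC on the higher side and CLDN, TNFRSF and BCL on the lower. These families overlap the lists of the report, so they are not separate evidence. Grouping by letters can also join unrelated genes, as under MGC, a prefix of clone names.

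Acute phase proteins did not pass as a list. Of 33 measured, 9 were higher and 1 was lower at an unadjusted p under 0.05. In the authors' deposited table, M-SAA3.2, a serum amyloid A and the lower gene, had a log2 fold change of -3.76 (p = 0.0259), while ITIH1 had 0.43 (p = 0.00153) and the pentraxin APCS 1.19 (p = 0.0105). None of the 3, chosen after their values were seen, passed an adjusted p of 0.05.

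The called genes were mostly lower in SLICK (58 of 71). The tables argue against a trend with gene length across all genes: log2 fold change and length had a Spearman rho of -0.0436, under the bound of 0.1 set in advance. The lengths of the called genes were not compared with those of other genes, so a length effect limited to them stays open. Scaling of the libraries stays open. An offset of 0.86 log2 units would be needed to leave 42 of the 71 lower, but genes called for large changes cannot turn under a small offset, so this decides nothing. Skeletal muscle in the FREE samples could not be judged by the bound set in advance. That bound asked for at least 5 abundant markers with a median of -0.5 or lower. Only 2 of the 6 measured markers averaged at least 0 log2 CPM. The median of the 6 was -0.16 (interval -0.41 to 0.09). They stood at a median of -1.19 log2 CPM against 3.02 for the genes that fell, so muscle RNA was scarce. That scarcity, which was not part of the bound, argues against muscle as the main source of the pattern. The genotype may be the source, but it is partly confounded with sire: SLICK has 5 daughters of each bull, and FREE has 1 of Blanco and 7 of Lone Ranger. Whether the authors' model held sire is not given in the sources used here, so sire stays open for this pattern and for those that follow.

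Interferon response genes were lower in SLICK, with a median of -1.09. Fewer leukocytes in SLICK would lower their markers alike, but the medians of all 4 leukocyte lists lay above the interferon median, by at least 0.69. Fewer neutrophils stay open as a part of it: their median was -0.40, and the list passed as lower with genes averaging at least 0 log2 CPM (adjusted p = 0.00911) and with the log2 fold change as the score (0.0345), but not otherwise (0.0951 to 0.272). Of 10000 random lists matched on expression, 0 had a median as low (lowest -0.09), although random lists lack the joint regulation of real ones. A candidate explanation that remains is a response, such as to infection, in some animals more than in others. The standard error implied by F had a median of 0.33 in the list, 3.49 times that of matched lists (0.09, with an upper bound of their central 95% of 0.11), which is consistent with strong differences between animals within the genotypes but does not show them.

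Metabolic and other lists, 11 in all, were higher in SLICK. A larger hepatocyte share in SLICK, taken evenly from all other cell types, would lower their markers alike. Against that even form, the endothelial median exceeded that of the cholangiocyte list by 0.51 (bootstrap interval over genes 0.13 to 0.92). The gap cannot decide on a larger hepatocyte share that comes mainly with fewer bile duct cells, so that stays open. A change in the bile duct cells themselves stays open too. A trend of fold change with expression level stays open for the group: with scores centred within expression levels, 5 of the 11 lists kept their call and 6 lost it. The 5 were fatty acid oxidation (difference from other genes 1.69 before and 1.02 after), xenobiotic metabolism, amino acid catabolism, the nuclear encoded respiratory chain (1.69 and 1.30) and the circadian clock, and the trend may account for part of the rise in these too.

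Sequence linked to the SLICK allele could change genes near PRLR, since daughters of 1 bull that share the allele share its surroundings. Within 5 Mb of PRLR, 10 of 39 genes (25.6%) had an unadjusted p under 0.05, against 2253 of 14082 elsewhere, and rotations of the gene positions gave p = 0.105. The excess did not pass, and 0 of the 39 genes had an adjusted p under 0.05. The nearest to it was CPLANE1 (chromosome 20, 37045115 to 37150094), with a log2 fold change of -0.55 and an adjusted p of 0.0568 in the authors' deposited table. RANBP3L (chromosome 20, 37936883 to 37991125) had 1.75 and 0.0818 in the authors' deposited table. On the whole chromosome, 1 of 212 measured genes passed an adjusted p of 0.05. This was ELOVL7, outside the window (18454411 to 18531445), with -3.06 and 0.0411 in the authors' deposited table. Whether linked sequence reaches that far was not tested. By the bound set in advance the share within the window counts against linked sequence. That bound was too strict a reading, because the share among 39 genes has a Wilson 95% interval of 14.6% to 41.1%, which holds the share elsewhere and also a much higher 1. The linked region therefore stays open.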
